A study of Homo sapiens with 4 samples.

How the data were processed

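Gene-level RNA-seq counts of 4 libraries from MDA-MB-231 cells were analysed, 2 given a control siRNA and 2 given an siRNA against hTrmt13. Per the labels' protocols, RNA was taken with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The deposited values are raw read counts per gene symbol, whole numbers that sum to different totals in each library, with no total or unassigned entry among them. The submitters' processing notes name cutadapt, STAR 2.5.2b, HTSeq 0.6.1 and limma, and the builds hg19 and GRCh37, without the role of each. The annotation, the strand setting and any filters are not given in the sources used here. Without a known strand setting, overlapping and antisense genes cannot be kept apart, and genes with near-identical copies may lose or share reads. The siRNA sequences and doses are not given there either. The ChIP-seq and CLIP-seq parts of the study were not used here.

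The table holds 28930 gene symbols, of which 10298 had no count in any library, and no symbol occurs more than once. Total counts ran from 9777267 to 13098985 per library, so a level of 1 CPM rests on about 10 to 13 counts. Intervals on counts are 95% exact binomial intervals of the ratio of depth-scaled counts, and they cover counting error only. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 40.4 in control and 44.5 in knockdown, over genes with a mean of at least 20 counts), so each library was counted as its own sample. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 libraries per group, every test borrows its estimate of spread across genes.

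Groups were taken from the sample labels. Counts were tested with edgeR 4.0.16 in R 4.3.3 using TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15, leaving 13022 genes) and the quasi-likelihood test of knockdown against control with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. CPM values are TMM-scaled and given as mean ± SD of 2 libraries, and the SE of a log2 fold change comes from the same fit. The common biological coefficient of variation was 0.246.

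A total of 31 gene lists were fixed before the data were examined, together with the design, the alternatives and the rule for named genes. They cover mesenchymal, epithelial, cell-cell adhesion, integrin, matrix, matrix protease, ATF4, aminoacyl-tRNA synthetase, endoplasmic reticulum, p53, DNA replication, mitosis, interferon, NF-kappaB, YAP/TEAD, TGF-beta, glycolysis, sterol, mitochondrially encoded, respiratory chain, ribosomal protein, ribosome biogenesis, tRNA modification, antigen presentation, heat shock, immediate early, apoptosis and histone genes, and markers of luminal epithelium, blood cells, and fibroblasts and endothelium. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 31 lists, and again with an estimated correlation and with fry. The form with an estimated correlation rests on the few residual degrees of freedom of these libraries and has little power to call a list. Named genes were TRMT13, the 10 genes higher and the 10 genes lower with the largest log2 fold change among called genes with a mean of at least 5 CPM and one direction in both pairs of equal replicate number, up to 4 called members per list with the smallest adjusted p (or up to 2 uncalled members with the smallest p, given as values), and SNAI2, CDH1, CDH2 and VIM whatever their test. The rule passed over genes known only by a clone name, and 1 other gene that is not reported here.

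On simulated counts for 13022 genes, with the real means, library sizes and dispersions and 200 changed genes, the edgeR test recovered 15 of 100 genes changed 2-fold and 83 of 100 changed 4-fold, and called 13 unchanged genes, which were 11.7% of its calls. These counts carried no shift by replicate number. With a shift estimated from the libraries and made identical in both groups, the same test recovered 0 and 0. The real deviations agreed less (r = 0.639 across genes), and there the test called 389 genes, so that simulation does not match these libraries. Changes of 2-fold, and with such a shift also of 4-fold, can therefore be missed in this design, and the share of false calls was above the nominal 5% in the simulation without the shift. In 1 simulation without that shift, camera called a list with a planted rise and did not call a list without one. Genes were drawn independently there, so it does not test the preset correlation on lists whose genes vary together. The correction for transcript composition was run on simulated values only to see that it takes out a planted GC trend.

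Alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in edgeR, no filter on low counts, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, thinning to the smallest library, a 2-fold minimum, the estimated correlation and fry. With 1 library left in an arm, its spread is assumed to equal that of the other arm. Added after seeing the data were a correction for GC content and transcript length (a spline with 5 degrees of freedom per library), the same correction with the block, and the list test without genes that carry the 3′ UTR words described in the closing section. Transcript sequences came from GENCODE 29, which is built on another genome build than the counts, so they were used for composition and words only and no coordinates are given. Of the tested genes, 12526 (96.2%) had a matched transcript, and of the changed genes 381 (97.9%).

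For the word scan, the log2 fold change was freed of trends on GC content, length and level, and genes with and without each 7-base word present in at least 100 genes were compared in the 3′ UTR (11951 genes) and the coding part (12236 genes). The threshold for the size of z was the 95th percentile of the largest value over all words in 1000 permutations of genes. In 20 simulations per region, with a fall of 0.3 log2 planted on the carriers of a word, that word was recovered as the lowest in 20. Smaller shifts were not simulated. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for this step.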

Results

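RNA sequencing was carried out on MDA-MB-231, a human triple-negative breast cancer cell line with mesenchymal features, after siRNA knockdown of hTrmt13 or treatment with a control siRNA. hTrmt13, encoded by TRMT13 (older symbol CCDC76), is a tRNA methyltransferase that places a methyl group on the ribose of tRNA. Each group held 2 libraries. The total counts were 9777267 and 12851510 in control replicates 1 and 2, and 10606149 and 13098985 in knockdown replicates 1 and 2. Mitochondrial genes took 6.88% and 4.82% of the counts in the control libraries and 6.26% and 5.18% in the knockdown libraries, so this share did not separate the groups. On log2 CPM the 2 control libraries correlated with r = 0.970 and the 2 knockdown libraries with r = 0.967 across genes, which are not independent replicates. The first principal component (64.2% of the variance) separated knockdown from control, and the second (29.8%) separated replicate 1 from replicate 2. The comparison asks which transcripts differ in level when hTrmt13 is reduced, as part of a study of its role in transcription.

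TRMT13 itself fell 4.05-fold in the knockdown, from 16.9 ± 2.79 CPM (SD, n = 2) to 4.16 ± 0.90 CPM (log2 fold change −2.02, SE 0.34, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0399). The single libraries held 14.9 and 18.9 CPM in control and 3.52 and 4.79 CPM in knockdown, so each library went with its label. Of 13022 genes tested, 389 (2.99%) changed, 134 of them higher and 255 lower in the knockdown. The changes called were large, with a median of 3.66-fold and a smallest of 2.06-fold. In all 389 the knockdown libraries lay on one side of the control libraries, a separation that 54.3% of all tested genes showed and that chance gives for 33.3%. At an unadjusted p under 0.05 there were 3121 genes, where chance gives 651. The smallest adjusted p was 0.0229, so the calls sit close to the threshold.

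**Figure D1:**
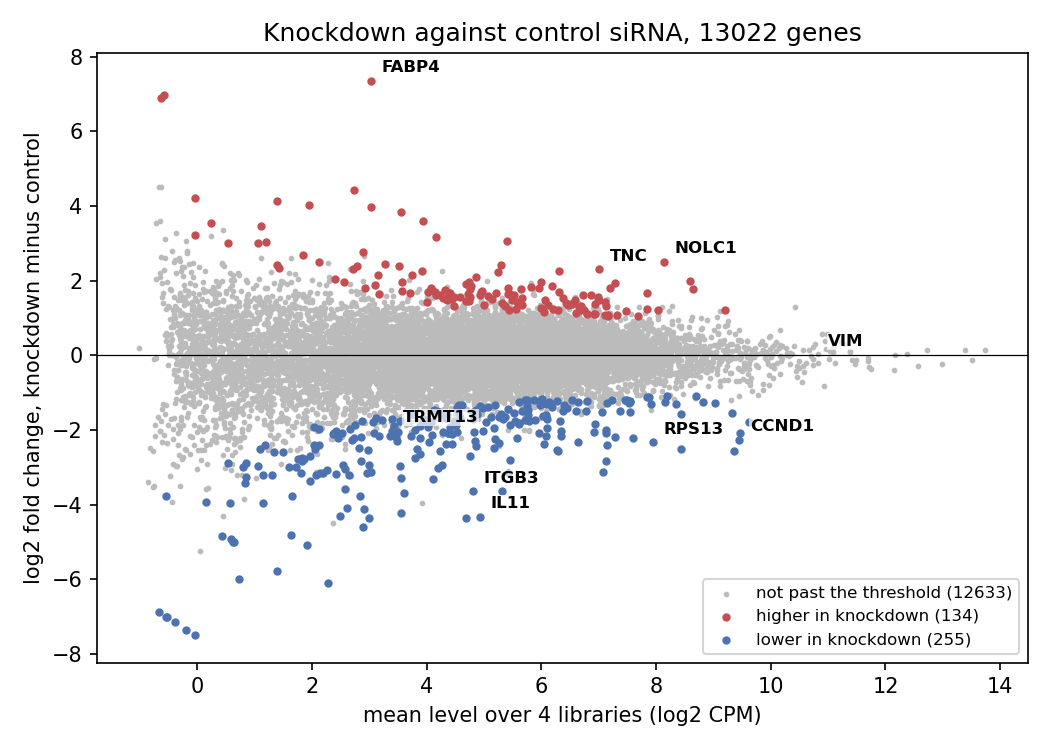
Log2 fold change (knockdown minus control) of 13022 genes against their mean level in log2 CPM over the 4 libraries. Red points are the 134 genes higher and blue points the 255 genes lower in knockdown, and grey points did not pass the edgeR threshold. TRMT13 lies at −2.02 and VIM at 0.02.

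Among genes with a mean of at least 5 CPM, the largest rises given here were those of FABP4, KRTAP2-3, FILIP1L, CPA4, EPB41L3, AOX1, PGM5P3-AS1, NOLC1, FAM227A and KRBA2. FABP4, a fatty acid-binding protein best known from adipocytes, had 2 counts in the control libraries together and 362 in the knockdown libraries, a depth-scaled ratio of 170.7 (95% exact binomial counting interval 46.9 to 1415). Its knockdown libraries differed from each other, at 25.1 and 7.34 CPM. KRTAP2-3, a hair keratin-associated protein with near-identical family members, went from 0.58 to 12.7 CPM (21.6-fold). CPA4, a carboxypeptidase, was 12.2-fold higher, and AOX1, an aldehyde oxidase, 8.43-fold higher. NOLC1, a nucleolar phosphoprotein, rose 5.69-fold from 84.2 ± 30.5 to 479.7 ± 17.8 CPM (SD, n = 2). FILIP1L was 14.4-fold, EPB41L3 9.02-fold, PGM5P3-AS1 6.77-fold, FAM227A 5.43-fold and KRBA2 5.22-fold higher. Over these 10 genes the edgeR adjusted p ran from 0.0229 for KRTAP2-3 to 0.0488 for FAM227A. The kit's strand and the counting setting are not given in the sources used here, so reads of the antisense gene PGM5P3-AS1 may not be separate from those of its partner.

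Among genes with a mean of at least 5 CPM and a symbol other than a clone name, the largest falls were those of RAB15, CACNA1H, BMF, IL11, PRSS1, MDFI, PCDH1, WTIP, SCUBE3 and ITGB3, between 24.1-fold for RAB15 and 12.4-fold for ITGB3. RAB15, a small GTPase of endosomal traffic, went from 14.2 ± 1.04 to 0.57 ± 0.26 CPM (SD, n = 2; edgeR adjusted p = 0.0229). IL11, a cytokine of the IL-6 family, went from 58.1 ± 18.7 to 2.89 ± 0.46 CPM (SD, n = 2), 19.9-fold lower. BMF, a pro-apoptotic BH3-only protein, was 20.5-fold lower, with control libraries at 75.9 and 22.3 CPM and knockdown libraries at 2.19 and 2.55 CPM. CACNA1H, a T-type calcium channel subunit, was 20.6-fold lower, and its control libraries also lay apart at 22.5 and 7.97 CPM. MDFI, an inhibitor of MyoD family factors, was 18.6-fold lower, PCDH1, a protocadherin, 17.0-fold, WTIP 13.7-fold and SCUBE3, a secreted glycoprotein, 12.97-fold. PRSS1, a trypsinogen whose reads can be shared with near-identical trypsinogen genes, was 19.7-fold lower.

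Of 37 integrin and focal adhesion genes tested, 5 fell and 0 rose (1 higher and 14 lower adjusted over the list alone). Integrin subunits led this list. ITGB3 fell 12.4-fold, ITGA7 8.87-fold and ITGB4 8.80-fold, the last from 241.9 to 27.5 CPM with control libraries at 346.0 and 137.7 CPM. PXN, the focal adhesion adaptor paxillin, fell 2.18-fold from 322.7 to 148.3 CPM. The list's median log2 fold change was −0.33 (camera adjusted p = 0.00594, and adjusted p = 0.829 with an estimated correlation), and −0.215 without control replicate 1. Of 32 cell-cell adhesion genes, 4 fell and 0 rose (3 higher and 7 lower adjusted over the list alone), with a median of −0.24 (camera adjusted p = 0.0193, and adjusted p = 0.829 with an estimated correlation). This call ended without knockdown replicate 2 (median −0.18, adjusted p = 0.123) and after a correction for GC content and transcript length that was added after seeing the data (−0.20, 0.0653), and the median was −0.42 without knockdown replicate 1. The 4 genes were PCDH1, ICAM1 (8.71-fold), the desmosomal cadherin DSC2 (2.97-fold) and CDH5, the endothelial cadherin, which had 112 counts in control and 2 in knockdown, a ratio of 59.4 (95% counting interval 16.1 to 496.4).

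Epithelial genes were also lower as a list. Of 23 tested, 3 fell and 0 rose (0 higher and 6 lower adjusted over the list alone), with a median of −0.43 (camera adjusted p = 0.014, and adjusted p = 0.891 with an estimated correlation), a call that ended without knockdown replicate 2 (−0.36, adjusted p = 0.123). DSP, the desmosomal plaque protein desmoplakin, fell 2.42-fold from 199.1 to 82.4 CPM, and ELF3, an epithelial transcription factor, fell 13.7-fold from 5.87 to 0.41 CPM. PRSS8, a membrane-anchored serine protease, had 65 counts in control and 2 in knockdown, a ratio of 34.5 (95% counting interval 9.16 to 290.6). CDH1, which encodes E-cadherin, had 1 count in each group and was not tested, so a difference was not detectable at this depth. Of 25 mesenchymal genes, 2 fell and 0 rose (3 higher and 7 lower adjusted over the list alone), namely the metastasis-associated S100A4 (3.02-fold) and the matrix protein SPARC (2.30-fold), and the list did not pass (median −0.43, camera adjusted p = 0.133, and adjusted p = 0.891 with an estimated correlation), although it passed without control replicate 2 (median −0.62, adjusted p = 0.00606) or knockdown replicate 1 (−0.64, 0.027) and its median was −0.115 without control replicate 1. VIM, which encodes vimentin, stood at 1795 ± 37.3 CPM in control and 1824 ± 29.2 CPM in knockdown (SD, n = 2), a log2 fold change of 0.02 (SE 0.19, edgeR adjusted p = 0.957). The repressor gene SNAI2 had a log2 fold change of 0.72 (SE 0.49, edgeR adjusted p = 0.411) at 2.08 and 3.42 CPM, and CDH2, which encodes N-cadherin, one of −0.38 (SE 0.63, edgeR adjusted p = 0.756) at under 1 CPM in each group, so neither difference exceeded the spread between replicates in this unpaired fit. In the pairs of equal replicate number, SNAI2 stood at 0.71 and 0.62 and CDH2 at −1.14 and 0.30, all on low counts.

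TGF-beta pathway genes were lower as a list, though not all of them, with 18 negative and 5 positive values. Of 23 tested, 3 fell and 0 rose (3 higher and 11 lower adjusted over the list alone), with a median of −0.87 (camera adjusted p = 0.00199, and adjusted p = 0.829 with an estimated correlation). The ligand gene TGFB1 fell 3.36-fold from 123.2 to 36.6 CPM. ID3 and ID2, inhibitors of helix-loop-helix factors that respond to BMP and TGF-beta signals, fell 5.37-fold and 4.20-fold. Of 23 YAP/TEAD targets, 3 fell and 0 rose (4 higher and 5 lower adjusted over the list alone). These were ANKRD1 (5.72-fold, from 585.9 to 102.4 CPM), NT5E, which encodes the ectonucleotidase CD73 (4.21-fold, from 1140 to 270.5 CPM), and CTGF (2.45-fold). That list as a set did not pass (median −0.20, camera adjusted p = 0.356).

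Cell cycle genes leaned lower. Of 32 DNA replication and G1/S genes, 31 had a negative log2 fold change and 1 fell past the threshold, CCND1, which encodes cyclin D1 (1 lower adjusted over the list alone). CCND1 fell 4.80-fold from 1159 ± 132.3 to 241.6 ± 2.43 CPM (SD, n = 2; edgeR adjusted p = 0.0229). The list's median was −0.80 (camera adjusted p = 0.000185, and adjusted p = 0.891 with an estimated correlation). It was −1.21 and −0.30 without control replicates 1 and 2, and −0.40 and −1.39 without knockdown replicates 1 and 2, with the call kept each time (largest adjusted p = 0.0319). In 32 mitosis genes the median was −0.55 and 30 values were negative, with 0 genes past the threshold, also over the list alone (camera adjusted p = 0.0627, and adjusted p = 0.915 with an estimated correlation). The smallest p in that list was that of CDC25B, at a log2 fold change of −0.39, and PLK1 stood at 46.7 and 125.4 CPM in the control libraries and at 23.3 and 60.4 CPM in the knockdown libraries. The mitosis median was 0.35 without control replicate 2 and 0.09 without knockdown replicate 1, while it was −1.03 without control replicate 1 (adjusted p = 1.55e-08) and −1.62 without knockdown replicate 2 (3.09e-07). Leaving out 1 library also leaves the replicate numbers unequal between the groups. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell 6.94-fold from 76.9 to 11.1 CPM, and TP53INP1 fell 4.24-fold. They were the 2 of 23 p53 targets past the threshold (1 higher and 2 lower adjusted over the list alone), and the list's median was −0.04 (camera adjusted p = 0.42).

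**Figure D2:**
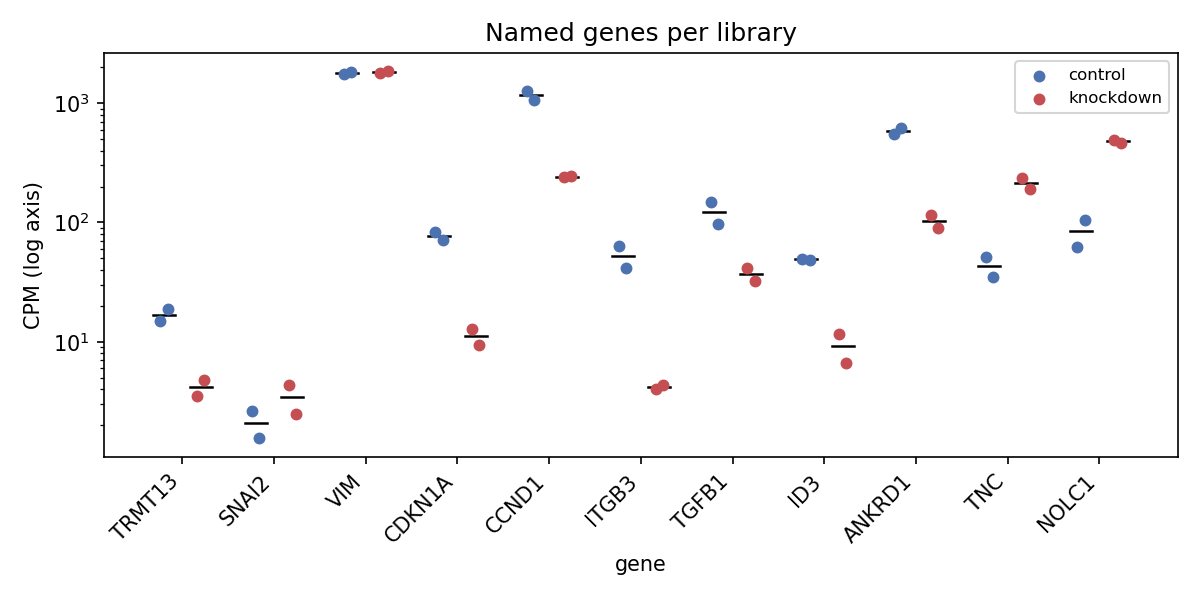
CPM per library, on a log axis, for 11 genes, with control libraries in blue, knockdown libraries in red and the group mean (n = 2) as a black bar. TRMT13, CDKN1A, CCND1, ITGB3, TGFB1, ID3 and ANKRD1 were lower and TNC and NOLC1 higher in knockdown, while SNAI2 and VIM did not pass the test.

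Ribosome biogenesis genes were higher as a list. Of 35 tested, 33 had a positive log2 fold change, with a median of 0.43 (camera adjusted p = 0.000303, and adjusted p = 0.891 with an estimated correlation), and 0.26 without control replicate 1 (adjusted p = 0.0203). Only NOLC1 rose past the threshold (2 higher adjusted over the list alone). Of 7 replication-dependent histone genes tested, 1 rose, HIST1H2AC (3.70-fold, from 3.65 to 13.5 CPM, 2 higher adjusted over the list alone), with a median of 1.23 (camera adjusted p = 0.014, and adjusted p = 0.829 with an estimated correlation). This call ended without control replicate 1 (median 0.63, adjusted p = 0.0784) or knockdown replicate 1 (0.80, 0.0783) and after the GC and length correction (0.95, 0.0736), and with no filter on low counts the median was 0.44 over 17 genes (0.0479). Histone genes share near-identical sequence, so their counts may be split between copies. Among 57 tRNA modification enzymes the median was 0.28, with 41 positive values and 0 genes past the threshold, also over the list alone (camera adjusted p = 0.0503). This list sits at the threshold. It passed with library size alone (camera adjusted p = 0.046), no filter on low counts (0.0457), a mean of 5 CPM (0.0436) and the replicate block (0.0393), among other alternatives. It did not with DESeq2 size factors (0.0519), upper-quartile scaling (0.0555) or an estimated correlation (0.891). Its median was 0.21 and 0.23 without control replicates 1 and 2, and 0.16 and 0.28 without knockdown replicates 1 and 2. The smallest p-values there were those of DUS1L (log2 fold change 1.25, edgeR adjusted p = 0.0815) and TRMT61B (0.82, edgeR adjusted p = 0.126). The 20 cytosolic aminoacyl-tRNA synthetases had a median of 0.25 with 0 genes past the threshold, also over the list alone (camera adjusted p = 0.0627, and adjusted p = 0.891 with an estimated correlation). That median was 0.16 and 0.33 without control replicates 1 and 2, and 0.28 and 0.20 without knockdown replicates 1 and 2. KARS stood at a log2 fold change of 0.71 and SARS at 0.53.

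In 62 cytosolic ribosomal protein genes the median was 0.05 (camera adjusted p = 0.639) and RPS13 alone changed (0 higher and 1 lower adjusted over the list alone), from 411.5 ± 49.4 to 82.5 ± 35.7 CPM (SD, n = 2), 4.98-fold lower. Processed pseudogenes of ribosomal protein genes can share reads with them. The median was −0.13 after the GC and length correction. In 36 nuclear-encoded respiratory chain genes the median was 0.08 (camera adjusted p = 0.244) and NDUFA4 fell 2.82-fold (1 higher and 1 lower adjusted over the list alone). That median was −0.067 after the GC and length correction, −0.023 without control replicate 1 and −0.015 without knockdown replicate 2, while without control replicate 2 it was 0.33 and the list passed (adjusted p = 0.0314, with 0.909 for the 4 libraries at an estimated correlation). In the 13 mitochondrially encoded genes the median was −0.13 with 0 changed, also over the list alone (camera adjusted p = 0.636), MT-ND6 standing at −0.95 and MT-ND2 at −0.39. After the GC and length correction that median was −0.37 (adjusted p = 0.163).

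Glycolysis and hypoxia genes were lower as a list, with 27 of 32 values negative, a median of −0.40 and 0 genes past the threshold, also over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.891 with an estimated correlation). The call ended without control replicate 1 (median −0.089, adjusted p = 0.64) or knockdown replicate 2 (−0.28, 0.315), and the median was −0.67 without control replicate 2 and −0.64 without knockdown replicate 1. PGAM1, a glycolytic mutase, stood at 474.6 and 233.0 CPM (edgeR adjusted p = 0.0552) and PGK1 at 1078 and 556.8 CPM (edgeR adjusted p = 0.103). In 25 sterol synthesis genes the median was 0.19 with 0 changed, also over the list alone (camera adjusted p = 0.356, and adjusted p = 0.95 with an estimated correlation), 0.52 without control replicate 2 (0.0107) and −0.12 without control replicate 1, TM7SF2 standing at 0.93 and PMVK at 0.82.

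Few matrix genes passed the threshold in the fit without the replicate block. With the block, 7 rose and 6 fell in the list of laminins, type IV collagens and other matrix, and 4 rose and 5 fell among matrix proteases and inhibitors. The values that follow are from the fit without the block. TNC, the matrix glycoprotein tenascin C, rose 4.98-fold from 43.2 to 215.0 CPM and COL8A1 rose 3.91-fold, the 2 changed genes of 27 in the list of laminins, type IV collagens and other matrix (3 higher and 2 lower adjusted over the list alone, median 0.15, camera adjusted p = 0.639). TIMP2, a metalloprotease inhibitor, fell 2.28-fold from 244.9 to 107.6 CPM, the 1 changed gene of 21 matrix proteases and inhibitors (2 higher and 3 lower adjusted over the list alone, median −0.16, camera adjusted p = 0.641).

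In the fit without the replicate block, between 0 and 3 genes of each stress and signalling list passed the threshold. With the block, the genes higher and lower were 4 and 6 for ATF4 targets, 1 and 5 for endoplasmic reticulum genes and 4 and 2 for heat shock proteins. They were 4 and 6 for immediate early genes and 7 and 7 for apoptosis regulators. The values that follow are from the fit without the block. Of 26 ATF4 targets and amino acid response genes, VLDLR fell 4.65-fold and ATF5 3.23-fold (0 higher and 2 lower adjusted over the list alone, median −0.09, camera adjusted p = 0.592). In 22 genes for endoplasmic reticulum chaperones and the unfolded protein response 0 changed, also over the list alone (median −0.14, camera adjusted p = 0.356), EDEM1 standing at −1.06 and SEL1L at −0.64. With a library left out, the median of these genes ran from −0.215 (without control replicate 1) to −0.024 (without control replicate 2). In 20 heat shock proteins 0 changed, also over the list alone (median 0.07, camera adjusted p = 0.791), DNAJB4 standing at 0.99 and HSPD1 at 0.95. Of 20 immediate early genes 3 fell, the phosphatase genes DUSP4 (2.36-fold) and DUSP6 (2.42-fold) and IER3 (4.14-fold), with a median of −0.04 (1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.554). Of 24 apoptosis regulators 1 rose and 1, BMF, fell (2 higher and 2 lower adjusted over the list alone). That list's median was 0.06 and its mean −0.14, and camera's direction was higher (adjusted p = 0.95).

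Immune lists did not pass as sets with the 4 libraries together. In 39 interferon-stimulated genes 0 changed, also over the list alone, with a median of 0.07, a mean of 0.03 and a camera direction of lower (adjusted p = 0.975, and 0.995 with an estimated correlation). They passed as higher without control replicate 1 (median 0.37, adjusted p = 0.0245) and as lower without control replicate 2 (−0.27, 0.0212). IRF1 stood at −1.69 (edgeR adjusted p = 0.0616) and IFIT1 at 1.36 (edgeR adjusted p = 0.127). Of 21 NF-kappaB targets and inflammatory cytokines only IL11 changed (0 higher and 1 lower adjusted over the list alone, median −0.50, camera adjusted p = 0.356). In 19 antigen presentation genes 0 changed over all genes tested (1 higher and 4 lower adjusted over the list alone, median −0.21, camera adjusted p = 0.244). Antigen presentation passed as lower without control replicate 2 (adjusted p = 0.0345) or knockdown replicate 1 (0.029), and NF-kappaB targets without control replicate 2 (0.0423), while with the 4 libraries and an estimated correlation both stood at adjusted p = 0.891. HLA-C, whose reads can be shared with other HLA genes, stood at −1.33 and PSMB8 at 0.97.

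Markers of cell types other than this line were low in number and mostly lower in the knockdown, beside the falls in epithelial and adhesion genes. Of 10 luminal breast epithelial markers 1 fell, the transcription factor gene SPDEF (6.53-fold, from 47.0 to 7.20 CPM), with 0 higher and 3 lower adjusted over the list alone and a median of −0.77 (camera adjusted p = 0.00537, and adjusted p = 0.829 with an estimated correlation). Of 5 fibroblast and endothelial markers 1 fell, CDH5, with 0 higher and 3 lower adjusted over the list alone and a median of −1.34, which does not depend on the size given to CDH5 since it is the lowest of them (camera adjusted p = 0.00199, and adjusted p = 0.829 with an estimated correlation), and of −0.84 over 6 markers without control replicate 1. Of 5 haematopoietic markers 1 fell, LAPTM5, a lysosomal membrane protein gene (3.59-fold, from 192.4 to 53.6 CPM), with 0 higher and 1 lower adjusted over the list alone and a median of −0.58 (camera adjusted p = 0.356).

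**Figure D3:**
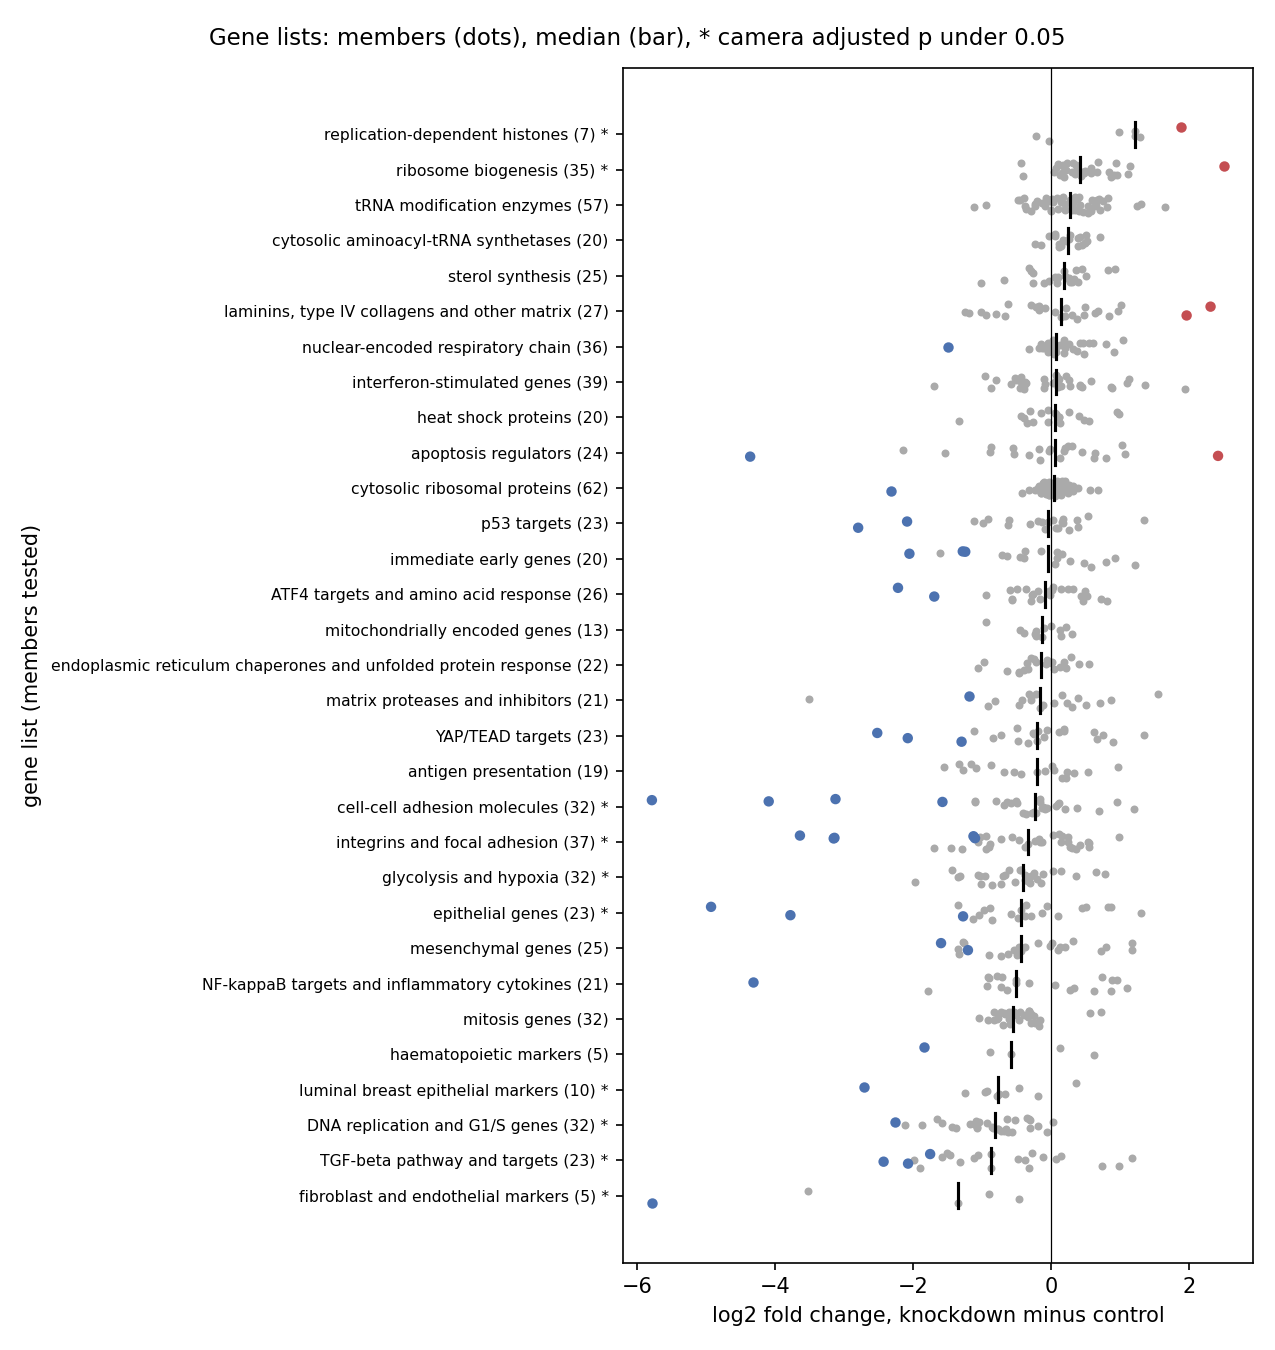
Log2 fold change (knockdown minus control) of the members of 31 gene lists, with the number tested in brackets. Red and blue dots passed the edgeR threshold, grey dots did not, black bars are list medians, and a star marks the 10 lists with a camera adjusted p under 0.05, of which 8 lay lower and 2 higher.

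Across the 10 lists with 0 genes past the edgeR threshold, 47 of 279 members had an unadjusted p under 0.05, DESeq2 called 16 and limma-voom 0. Of all 13022 tested genes 3121 had such a p, a larger share than in these lists. Of the 10 lists called with camera's preset correlation, 0 were called with an estimated correlation. That form of the test rests on the few residual degrees of freedom of so few libraries, so it could hardly call a list. Integrins (estimated correlation −0.0231) and cell-cell adhesion (−0.0281) lost their calls although these estimates lay under the preset 0.01. The other called lists had estimates above it, from 0.0499 for TGF-beta genes to 0.7278 for glycolysis and 0.8265 for DNA replication. Where genes of a list vary together that much, the preset gives too small a p-value, so low power is not the only reason for these lost calls. Directional fry, which asks whether a list moves on balance in one direction, called 1, integrins and focal adhesion (adjusted p = 0.0136). The mixed form of fry, which lets members move in either direction, called 19 lists. Against 389 in the main fit, 5227 genes changed with the replicate number as a block (2517 higher, 2710 lower), so the counts of 0 per list hold only without the block. The number was 1949 with no filter on low counts, 1129 with DESeq2 and 1625 with the GC and length correction, and it also rose with each library left out.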

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

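The correction for GC content and length, that correction with the block, and the list test without word carriers were chosen after seeing the data. TRMT13 stayed lower and past the threshold in every setting run, with log2 fold changes from −1.81 to −2.26. The number of genes changed stayed within 1.5 times of 389 with DESeq2 size factors (401), upper-quartile scaling (423), library size alone (351), limma-voom (325), thinning (330) and a mean of at least 5 CPM (272), and a 2-fold minimum moved nothing because each called gene already passed it. Over the planned scalings the median of all genes shifted by under 0.1 on the log2 scale. Counts moved with no filter on low counts (1949 genes changed, 826 higher, 1123 lower), with DESeq2 (1129, 455 and 674) and with the GC and length correction (1625, 749 and 876). The cause was not tested for these. Leaving out each library in turn gave 678 to 935 genes changed, 198 to 363 higher, 407 to 572 lower and 8 to 18 lists called, the 18 without control replicate 2. Of 53 named called genes, 50, 51, 53 and 46 stayed past the threshold without control replicate 1, control replicate 2, knockdown replicate 1 and knockdown replicate 2. The calls lost were SPARC, S100A4 and DSP without control replicate 1, SPARC and DSC2 without control replicate 2, and SPARC, S100A4, PRSS8, DSC2, PXN, TIMP2 and CTGF without knockdown replicate 2. Named genes also lost their call in other settings, 7 with limma-voom, 5 with thinning, 4 with a mean of at least 5 CPM and 2 with library size alone. With an estimated correlation 0 lists were called, with directional fry 1, and without carriers of the 3′ UTR words 5.

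Replicate numbers are shared between the groups, but the labels do not say what a number stands for. Deviations of equally numbered libraries from their group means correlated across genes (r = 0.639). With the replicate block, 5227 genes changed (2517 higher, 2710 lower), and 6364 (3101 higher, 3263 lower) with the GC and length correction in the same fit. The block added the calls of mitosis genes (median −0.63, 21 lower, 1 higher, adjusted p = 6.85e-05) and tRNA modification enzymes (15 higher, 3 lower, 0.0393) and changed no other list call. With it 25 DNA replication genes were lower (median −0.83), 15 glycolysis genes lower and 2 higher, 16 ribosome biogenesis genes higher and 2 lower, and 7 aminoacyl-tRNA synthetases higher, so counts of 0 per list hold only without the block. With the block and the GC and length correction the calls of integrins (0.0673), cell-cell adhesion (0.0951) and histones (0.0673) ended. In simulated counts for 13022 genes with a shift by number made identical in both groups, the edgeR test without the block recovered 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold, while with the block it recovered 82 and 95 and called 8 unchanged genes. A fully shared shift favours the block in advance, and the real deviations correlated at 0.639. The size of this gap therefore does not carry over to these libraries.

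Results that turned sign had not passed the test. Apoptosis regulators had a median of −0.031 with no filter, 0.013 with the GC and length correction, 0.05 without word carriers and −0.067 to 0.073 with a library left out. Interferon-stimulated genes were at 0.047 with the block (where camera's direction turned), −0.038 after the GC and length correction, −0.082 without word carriers and between −0.36 and 0.37 with a library left out. With a library left out, the medians ran from −0.17 to 0.11 for matrix proteases, −0.51 to −0.01 for NF-kappaB targets (where camera's direction turned), −0.12 to 0.52 for sterol synthesis, −0.30 to 0.12 for mitochondrially encoded genes, −0.11 to 0.21 for heat shock proteins, −0.20 to 0.42 for laminins and other matrix, −1.62 to 0.35 for mitosis genes, −0.059 to 0.12 for ribosomal proteins, −0.023 to 0.33 for the respiratory chain, −0.16 to 0.14 for ATF4 targets, −0.24 to 0.014 for antigen presentation, −0.31 to 0.11 for immediate early genes, −0.72 to 0.02 for haematopoietic markers, and CDH2 ran from −1.15 to 0.073. After the GC and length correction VIM was at −0.053 (−0.054 with the block) and ribosomal proteins at −0.13 (−0.12 with the block). The p53 targets were at 0.008 there. Without word carriers the matrix list was at −0.011, ATF4 targets at 0.03, heat shock proteins at −0.043, p53 targets at 0.027, immediate early genes at 0.093, antigen presentation at 0.014 and endoplasmic reticulum genes at 0.009. The cause was not tested. At this depth CDH1, with 1 count per group, and other genes near the floor could not be compared.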

Other observations

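The scan of symbol families, the list of cilia genes, the scan of 7-base words, the tests that carry a word from the replicate 1 libraries to the replicate 2 libraries and the GC and length correction were chosen only after results had been seen. Genes of intraflagellar transport, the machinery that moves cargo along cilia, were higher in the knockdown as a family. All 14 tested members with the IFT symbol had a positive log2 fold change, with a median of 0.88, and 2 passed the threshold, IFT27 (1.79, SE 0.30, edgeR adjusted p = 0.0399) and IFT57 (1.22, SE 0.23, edgeR adjusted p = 0.0467). IFT27 stood at 8.35 and 6.81 CPM in the control libraries and at 29.4 and 22.8 CPM in the knockdown libraries, and IFT52 at 19.0 and 27.8 against 54.8 and 58.0 CPM (edgeR adjusted p = 0.0594). Among 119 symbol families of at least 12 tested genes the camera adjusted p was 6.53e-05, and adjusted p = 0.971 with an estimated correlation. After the GC and length correction the family's median was 0.82 with 6 members higher (camera adjusted p = 0.000448, and adjusted p = 0.97 with an estimated correlation). Only 2 of the 14 members lack the higher-side words of the scan, with a median of 0.63 in the main fit. So few members cannot separate the family's rise from those words. Such words are common, in the coding part of 63.9% of the tested genes not called changed. A list of 44 other genes of ciliary transport and the transition zone was written after the family was seen, without the cilia genes noticed among the called ones. Of its 43 tested members 37 were positive and 0 passed the edgeR threshold (median 0.50, camera p = 1.54e-05, and p = 0.0357 with an estimated correlation). At an unadjusted p under 0.05 there were 13, against 3121 of all 13022 tested genes, and DESeq2 called 4 and limma-voom 0. Its ciliary transport genes belong in part to the same machinery as the IFT family, so the list is not separate support. Long non-coding RNAs with the LINC symbol were the other family past the threshold, with 118 tested, 4 higher, 0 lower and a median of 0.50 (camera adjusted p = 0.00749, and adjusted p = 0.971 with an estimated correlation), and after the GC and length correction their median was 0.38 and the call ended (adjusted p = 0.13).

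Genes lower in the knockdown were marked by short words in the 3′ UTR. In the 3′ UTR 12 words were past the permutation threshold on the lower side, and 10 of them share the bases GCATA, led by TGCATAA (1172 genes, mean difference −0.19 log2, z = −7.87, permutation p = 0.001 over all words, the smallest that 1000 permutations can give). The scan removes GC and length trends before z is taken, also within a group, so it cannot test those trends. A remaining difference in base composition that also sets replicates of a group apart is argued against. One shared by both libraries of a group cancels between replicates, so it was not tested. The z of TGCATAA reached only 2.54 in the contrasts of replicate 2 against replicate 1 within a group, under the thresholds of 4.62 and 4.68, and 0 words of the 3′ UTR passed there. TGCATAA was also the lowest word in the replicate 1 libraries alone, and in the replicate 2 libraries its z was −8.18, as binding by a small RNA of the knockdown group, such as the siRNA, could give. TGCATAA itself lies in neither the coding part nor the 3′ UTR of TRMT13. The strongest per-gene shift was that of ACGCATA (136 genes, −0.42 log2, z = −6.32), of whose carriers 13 (9.56%) fell and 0 rose, against 2.05% and 1.0% of all genes with a 3′ UTR. Of the 140 carriers in the coding part 10 (7.14%) fell and 0 rose, against 2.04% and 1.0%. In the coding scan the lowest word was GCATAAA (610 genes, −0.15 log2, z = −4.81, permutation p = 0.028). Other coding words reached z = −6.2 and −5.91 between replicates of the control and the knockdown group. The permutation threshold therefore does not bound differences between replicates in the coding part, and this word is weak evidence. ACGCATA and GCATAAA both lie in the coding part of TRMT13, at its 1 place with GCATA, so they count as 1 match. That coding part holds 7.88% of all possible 7-base words, a share that applies to 1 word named in advance. Several words past the threshold were looked up, most of them sharing GCATA, so a match by chance is likelier than that. The match could come from an siRNA seed, but it does not count as evidence for one. TGCATAA as a whole is absent, but its bases GCATAA lie at that place within GCATAAA, so its absence counts little against a seed. Without the siRNA sequence this explanation stays open.

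On the higher side, words with the bases GGAGA marked genes in the coding part (4 of 5 words past the threshold) and in the 3′ UTR (4 of 6), led by CGGAGAA in coding parts (1408 genes, 0.16 log2, z = 7.32). For TCGGAGA, the highest word of the replicate 1 libraries, a remaining difference in base composition that also sets replicates apart is argued against. One shared by both libraries of a group was not tested here either. The z of TCGGAGA within a group was at most 2.45, although 7 and 13 other words of the coding part did pass in those contrasts. Its z in the replicate 2 libraries was 6.07 (threshold 4.63), as a small RNA present in the control group, such as the control siRNA, could give. Coding words reached z = −6.2 and −5.91 between replicates of a group, so this value too is weak evidence. GGAGAAT, the highest 3′ UTR word of the replicate 1 libraries, had z = 6.34 in the replicate 2 libraries (threshold 4.69). With a single siRNA contrast per group and no siRNA sequence in the sources used here, changes through hTrmt13 and changes through either siRNA stay open for any gene above, and without genes that carry the 3′ UTR words 5 of the 10 called lists kept their call (epithelial genes, DNA replication, TGF-beta, ribosome biogenesis and luminal markers), in a test with 6657 genes instead of 13022. The other calls ended there for integrins (median −0.33 before and −0.16 after, adjusted p = 0.163, 16 genes left), cell-cell adhesion (−0.24 and −0.27, 0.0764, 13 left), glycolysis (−0.40 and −0.28, 0.226, 16 left) and histones (1.23 before and after, 0.163, 3 left), and the fibroblast and endothelial list was not tested there. Fewer genes alone can end a call.

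Libraries of equal replicate number deviated together from their group means, with a correlation of 0.639 across genes. In the control group replicate 2 minus replicate 1 fell with transcript GC content (Spearman's rho −0.355 across genes, which are not independent replicates), and in the knockdown group more steeply (−0.667). A GC and length trend is argued against as the whole of it, because the correlation was 0.594 after the trend was removed, and so is library size, because it was 0.631 after thinning each library to the smallest total. A split of the 4 libraries by replicate number gave 0 changed genes with edgeR (953 at an unadjusted p under 0.05, 80 with DESeq2, 0 with limma-voom) against 389 for knockdown and control, and 3 splits are too few for a share under 0.05. No biological explanation was tested, since the labels do not say what a replicate number stands for.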
